A study of Mus musculus with 2 samples.

How the data were processed

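Trimethylation of lysine 4 of histone H3 (H3K4me3), a histone mark found at transcription start sites, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse forebrain on postnatal day 0. The tissue came from healthy pups of a B6NTac and B6NCrl background, with males and females pooled. There is 1 group with 2 biological replicates. Replicate 1 was a pool of 15 mice per the labels, and the number of mice in replicate 2 is not given in the sources used here. The labels give a size range of 300 to 500.

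The deposited data analysed here are 4 peak lists in narrowPeak format on mm10. Peaks were called on replicate 1, on replicate 2 and on both pooled, and the fourth list holds the replicated peaks, derived from the other lists per the file headers and the text files deposited with them. Every replicated peak has the position and values of a pooled peak, so values from this list are those of the pooled data and carry no replicate error. The aligner, the peak caller, their versions and the calling thresholds are not given in the sources used here. Read numbers are also not given, so the sequencing depth of each replicate is unknown and no interval that needs it is printed. A difference in depth would change how many weak peaks each list holds.

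Each deposited peak carries a score, which was not used to select peaks. It also carries an enrichment signal given by the authors, 1 value per peak, and what this signal is relative to is not stated. The authors' −log10 q-value of each peak was used only for a stricter threshold. Enrichment signals were used to describe and rank peaks within 1 list and to restrict the list to peaks above the median signal. Signals were also correlated between the replicates, and median signals of gene lists were compared with those of random lists.

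Peaks on the 21 chromosomes were kept, and peaks on other sequences were left out. Peaks 1 kb or less apart were merged into domains, and a domain took the highest signal of its peaks. Transcript starts came from GENCODE release M21, on the same build, with 55413 genes. A protein-coding gene was counted as marked when a peak lay within 1 kb of any of its annotated starts, and its domain width was that of the widest such domain. A domain over 5 kb from every start was called distal. Promoter CpG content was taken from 1000 bp centred on each start, using the start with the highest observed-to-expected ratio. CpG-rich promoters had a ratio of at least 0.75 and a GC fraction of at least 0.55, and CpG-poor promoters had a ratio below 0.48. Broad domains were the widest 5% of domains at coding starts.

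The share of peaks of each replicate that overlap the other by at least 1 bp was set beside 100 random placements of the same intervals on the same chromosome. Marking was compared between CpG classes, and between each of 29 fixed gene lists and all other coding genes, by two-sided Fisher's exact tests. P-values over lists were adjusted by the Benjamini-Hochberg method. Each list was also set beside 10000 random lists with the same number of genes in each CpG class. The median domain width of lists with at least 5 marked members was compared with 10000 random lists of marked genes by a two-sided permutation test, whose smallest possible p is 0.0002. List membership among broad domains was compared with other marked genes by Fisher's exact test. Genes, not animals, are the units of all these tests, and neighbouring genes are not independent. With 1 group there was no comparison between conditions.

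The lists, tests and 72 alternatives were fixed before the data were examined. The named genes follow a rule fixed then. It takes up to 3 members of each list with the widest domains and up to 3, in alphabetical order, with no peak in the replicated list or either replicate. It adds the genes at the 20 widest domains, the 5 widest distal domains, the 5 widest domains in 1 replicate only, and a fixed set of genes. Further genes named by their values were chosen after those were seen. Alternatives were each replicate alone, stricter peak thresholds, the pooled list, other start windows, merging distances, overlap rules and limits for broad and distal domains, and CpG-matched lists. Another 4 were added after the data were seen: 1 gene per domain, and genes with shared starts left out of the width, broad-domain and coding-share results.

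Further tests used the share of 32-base words around a start that occur once on the chromosomes, taken every 10 bp, and the starts of the RefSeq annotation of the same build. They also used 10000 random lists in which each gene was replaced by 1 of the 50 marked genes nearest in domain width.

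Fisher's exact test of marking and the width test were checked on simulated lists of randomly drawn genes, over 21938 coding genes. The tests against CpG-matched lists and of broad domains were not checked in this way. All 5 lists with every member marked and all 5 with a share of 0.1 marked were called, as were all 10 lists made 2.5 times wider. None of 20 lists left unchanged in marking, and none of 15 left unchanged in width, was called. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pysam 0.24.0, numba 0.67.0, samtools 1.23.1 and matplotlib 3.10.9.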

Results

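H3K4me3 was mapped in the forebrain of newborn mice in 2 biological replicates, each a pool of animals. The lists held 29382 peaks in replicate 1, 26452 in replicate 2, 28755 in the pooled data and 22693 in the replicated list. Peaks covered 34.7 Mb in replicate 1 and 35.3 Mb in replicate 2. Read depth is unknown. Shares below refer to the replicated list unless a replicate is named, and widths given with an SD are means of the 2 replicates.

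The replicates marked nearly the same places. Of the replicate 1 peaks, 83.6% (95% exact binomial interval 83.2 to 84.0) overlapped a replicate 2 peak, and 87.6% (87.2 to 88.0) of replicate 2 peaks overlapped a replicate 1 peak. Random placement gave 2.46% and 2.62%. Among coding genes, 14236 were marked in both replicates, 141 in replicate 1 only and 107 in replicate 2 only. Domain widths correlated between replicates across 19382 domains matched one to one (Spearman's rho = 0.962), and signals did so with rho = 0.948. Domains are not independent replicates, so these values describe the lists only. The overlap rule moved the shares, and a required overlap of 50% of both peaks gave 69.2% and 76.8%.

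**Figure D1:**
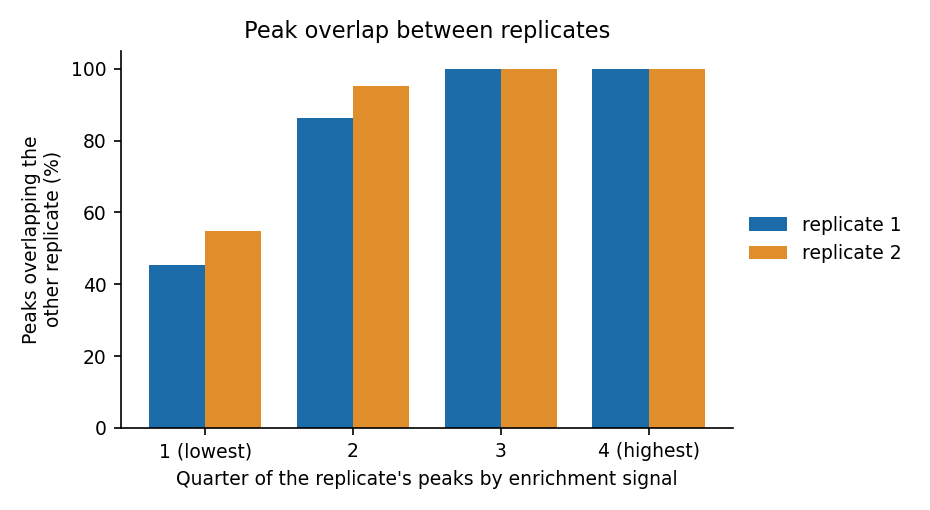
Share of peaks that overlap the other replicate (%, bars from 0) for 4 groups of about equal size, from the lowest (1) to the highest (4) enrichment signal in the replicate's own list, with replicate 1 in blue and replicate 2 in orange. In group 1, 45.4% of replicate 1 peaks and 54.8% of replicate 2 peaks were shared, and in groups 3 and 4 every peak was.

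Peaks found in 1 replicate only were narrow and weak. There were 4814 in replicate 1 and 3286 in replicate 2, with median widths of 203 and 242 bp against 1186 and 1309 bp for shared peaks. Within 1 kb of a start lay 24.3% and 25.7% of them, against 69.3% and 70.6% of shared peaks. The 5 widest such domains lay near Arhgef17 (chromosome 7, 100926769 to 100929407, 2639 bp), Gm26485, Pea15a and Nav2 in replicate 2 and near Zfp281 in replicate 1. Requiring a −log10 q of 3 or more in both lists left 1999 and 2079 unshared peaks.

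Most of the mark lay at gene starts. The replicated peaks formed 20235 domains, of which 74.7% (95% exact binomial interval 74.1 to 75.3) lay within 1 kb of an annotated start, against 10.9% for random placement. The share was 70.8% ± 1.58 (SD, n = 2) in the replicates. In total 14320 of 21938 coding genes were marked (65.3%), and 65.5% ± 0.11 (SD, n = 2) in the replicates. Their median domain was 2.08 kb wide. Actb, which encodes cytoplasmic beta-actin, had a domain of 4.27 kb ± 0.361, and the glycolytic gene Gapdh had one of 2.92 kb ± 0.0742 (SD, n = 2).

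Promoter sequence separated marked from unmarked genes. Of CpG-rich promoters 6664 of 6698 were marked (99.5%), of intermediate ones 94.4% and of CpG-poor ones 1314 of 8525 (15.4%). The odds ratio of rich against poor was 1076 by Fisher's exact test, and it ranged from 970.4 to 1136 in the single replicates. Restricting the list to peaks above the median signal lowered it to 267.7.

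Genes of the neuronal lineages were marked nearly throughout. All 16 neural progenitor genes, all 17 cortical glutamatergic genes, all 22 pan-neuronal and synaptic genes, all 24 glutamate receptor genes and all 17 forebrain patterning factors carried the mark. So did 23 of 24 GABAergic and striatal genes, the exception being Vip, which encodes a neuropeptide of interneurons. All 15 immediate early genes, 21 cell cycle genes, 20 housekeeping genes and 16 genes of the H3K4 methylation machinery were marked as well. These 10 lists were marked more often than other coding genes, with adjusted p from 0.00022 to 0.0037 by Fisher's exact test. Against lists matched on CpG class, the share stayed higher for cortical glutamatergic genes, pan-neuronal genes and glutamate receptors. Their adjusted p in the permutation test was 0.013, 0.0036 and 0.00083. CpG differences within a class were not removed. The other 7 lists did not pass this permutation test. All of these but GABAergic and striatal genes were marked in full, against 91.9 to 98.9% expected. Their share could be no higher, so the test could not have called them. With 1 start per gene the call was lost for the H3K4 methylation machinery (87.5%, adjusted p = 0.059, Fisher's exact test). Among peaks above the median signal, the call was also lost for progenitors (adjusted p = 0.11, Fisher's exact test), glutamatergic genes (0.84), patterning factors (0.84), immediate early genes (0.057) and cell cycle genes (0.15). GABAergic and striatal genes were then marked in 33.3% of cases (0.091 in the same exact test).

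Astrocyte, oligodendrocyte, vascular and choroid plexus lists were marked in part, and none passed Fisher's exact test (adjusted p from 0.17 to 1). The mark was found at 12 of 14 astrocyte genes, including Slc1a2, a glutamate transporter, but not at Gfap, an intermediate filament, or S100b. Against CpG-matched lists the astrocyte share was higher (permutation adjusted p = 0.031). Of the oligodendrocyte precursor genes 7 of 8 were marked, Gpr17 being the exception. Myelinating oligodendrocyte genes were marked in 5 of 12 cases, with a domain of 2.11 kb ± 0.0212 (SD, n = 2) at Mbp and none at Aspa, Ermn or Mag. Endothelial and pericyte genes were marked in 9 of 14 cases, and in 12 and 10 in the replicates. Tek and Slco1c1 were unmarked. For choroid plexus and ependyma the count was 5 of 8, with no peak at Ttr, which encodes transthyretin. GABA-A receptor genes were marked in 14 of 19 cases, with Gabra6, Gabrp and Gabrr1 among the rest, and erythroid genes in 4 of 10, and neither list passed (adjusted p = 0.7 and 0.15, Fisher's exact test). Among peaks above the median signal, oligodendrocyte precursor (12.5%), endothelial and pericyte (14.3%) and erythroid genes (10%) passed as marked less often (adjusted p = 0.046, 0.011 and 0.016, Fisher's exact test).

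Effector genes of other tissues and cell types were marked rarely. None of 19 liver genes, Alb among them, carried a replicated peak (adjusted p = 1.3e-08, Fisher's exact test), and 1 did in replicate 1. Of the olfactory receptor genes 3 of 1135 were marked (odds ratio 0.0012), of the vomeronasal receptor genes 1 of 329 (adjusted p = 6.3e-150) and of the keratin genes 8 of 110 (1.3e-36), both by Fisher's exact test. Germline genes were marked in 2 of 19 cases (6.9e-06), muscle genes in 4 of 18 (0.00061), microglial genes in 3 of 16 (0.0006) and lymphocyte genes in 2 of 14 (0.00051), in the same exact test. Liver, muscle, microglial and lymphocyte lists did not pass against CpG-matched lists (permutation adjusted p from 0.22 to 0.47). The liver list already had the lowest share possible, against 15.3% expected (unadjusted permutation p = 0.082), so it could not have passed. Several marked members share their domain with another coding gene: Mylpf with Tbc1d10b, Ckm with Klc3, Foxp3 with Ppp1r3f, Gdf9 with Uqcrq and Vmn1r4 with Nt5c3.

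Hox genes and non-neural lineage factors were marked less often than genes of like CpG class. Of the Hox genes, which pattern the trunk and hindbrain, 20 of 39 were marked, against 90.3% expected from CpG-matched lists (permutation adjusted p = 0.00083). Non-neural lineage factors were marked in 22 of 36 cases against 80.2% expected (0.00083 in the same permutation test). Hnf4a, Hnf1a and Hand1 had no peak, whereas Myod1, a muscle determination factor, had a domain of 1.77 kb ± 0.0926 (SD, n = 2). Against all other genes neither list passed Fisher's exact test (adjusted p = 0.14 and 0.7). With a −log10 q of 3 or more the Hox list did (adjusted p = 0.011, Fisher's exact test), and with 1 start per gene the non-neural list did (0.026). Midbrain, hindbrain and spinal factors were marked in 15 of 19 cases and pluripotency factors in 7 of 12, with no peak at Nanog, and neither passed in the replicated list (Fisher's exact adjusted p = 0.3 and 0.82, CpG-matched permutation adjusted p = 0.65 and 0.45). Among peaks above the median signal both passed as marked less often, at 10.5% and 16.7% (adjusted p = 0.00059 and 0.028, Fisher's exact test), as did Hox genes (5.9e-11) and non-neural factors (1.3e-07).

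**Figure D2:**
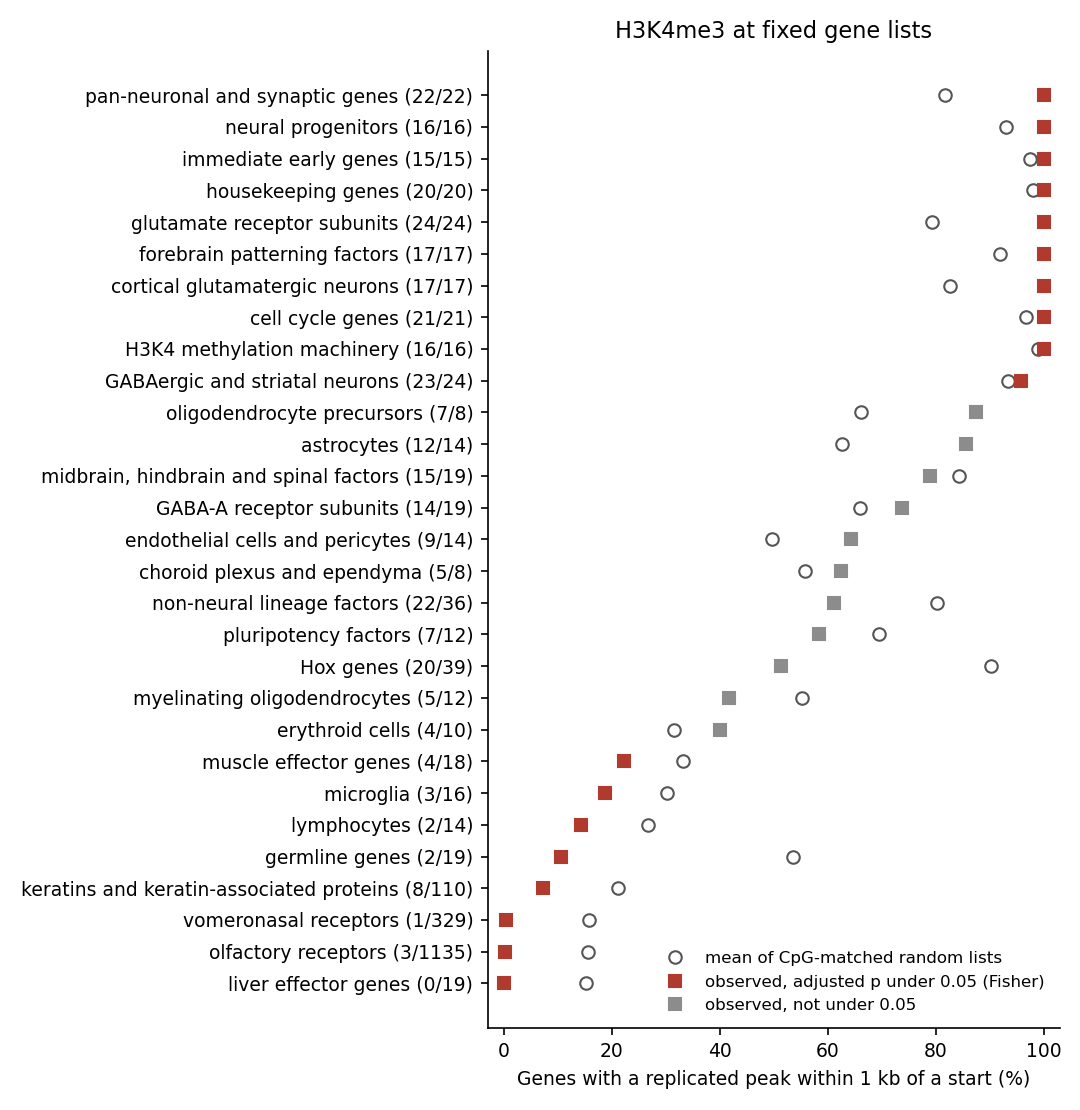
Share of each list's genes with a replicated peak within 1 kb of a start (%, squares, with marked and total genes in brackets) and the mean share of CpG-matched random lists (open circles). Red squares have an adjusted p under 0.05 in Fisher's exact test; Hox genes lie at 51.3% against 90.3% for matched lists.

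The 20 widest domains at coding genes ran from 13.7 to 27.6 kb in the replicated list. The widest domain of all covered the start of the noncoding gene C130071C03Rik on chromosome 13 (83713122 to 83742926), spanning 29.8 kb in the replicated list, 29.8 kb in replicate 1 and 32.5 kb in replicate 2. Among coding genes Meis2 had the widest in the replicated list, with a replicate mean of 28.0 kb ± 1.84 (SD, n = 2; chromosome 2, 116048968 to 116076547). Pou3f3 had 24.3 kb ± 0.341 and the domain of Foxg1, a regulator of telencephalic growth, 23.8 kb ± 1.01. Dlx6 had 23.8 kb ± 6.95. The domain shared by Dlx1 and Dlx2, factors of GABAergic neurons, spanned 23.2 kb ± 0.112 on chromosome 2. Satb2, a factor of callosal projection neurons, had 20.3 kb ± 0.921, Bcl11b 16.2 kb ± 0.0891 and Tbr1 13.6 kb ± 0.119. Also among the 20 widest at coding genes were Nfib, Mn1, Nr2f1, Nr2f2, Otx1, Pax6, Pou3f2, Zeb2, Tnrc18, Bcl11a, Mef2c and Myt1l. Among these 20, the replicates differed most at Nr2f1 (SD 5.28 kb), Nr2f2 (6.29 kb) and Dlx6 (6.95 kb).

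**Figure D3:**
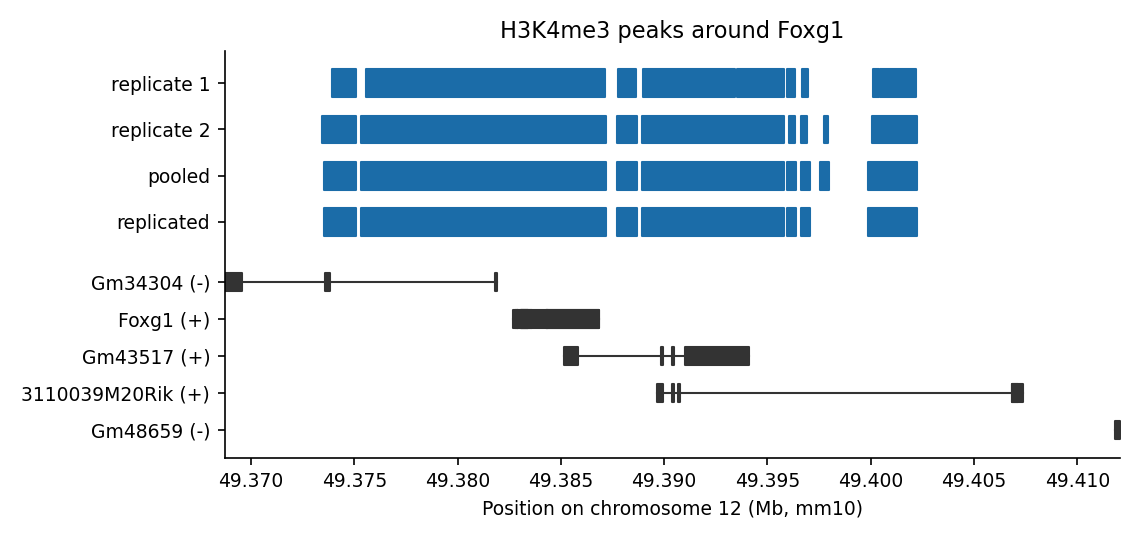
Peaks of each list (blue) and gene models (black, exons as boxes, strand in brackets) along chromosome 12 in Mb on mm10. In the replicated list the Foxg1 domain runs from 49373516 to 49397056. It also covers Gm43517 and the starts of Gm34304 and 3110039M20Rik.

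Domain width also differed between lists. In the permutation test 8 of 21 lists had wider domains than random lists of marked genes. Forebrain patterning factors had a median of 10.9 kb, GABAergic and striatal genes 7.27 kb, cortical glutamatergic genes 6.77 kb and neural progenitors 4.87 kb. Pan-neuronal genes had 4.46 kb, immediate early genes 4.36 kb and glutamate receptors 4.09 kb, each of these 7 with a permutation adjusted p of 0.00042. The widths depended on the merging distance. Without merging the medians were 7.17 kb for patterning factors, 4.35 kb for GABAergic and striatal genes and 5.79 kb for cortical glutamatergic genes, and with a 3 kb gap the GABAergic and striatal median was 11.4 kb. Astrocyte genes had 3.21 kb (permutation adjusted p = 0.013). This call was lost when genes with shared starts were left out, an alternative chosen after seeing the data. The median was then 2.79 kb (permutation adjusted p = 0.16). Narrower domains were found at Hox genes (0.858 kb), non-neural lineage factors (1.01 kb), keratins (0.768 kb), myelin genes (1.06 kb) and pluripotency factors (1.19 kb), with permutation adjusted p from 0.00042 to 0.018. The Hox median was 0.43 kb in replicate 1 and 0.605 kb in replicate 2, with the call kept in each. The median was 1.55 kb for non-neural factors in the pooled list and 0.47 kb for keratins with 1 start per gene, with both calls kept. Median signals were 4.81 at Hox genes, 5.68 at non-neural factors, 7.46 at keratins and 9.58 at pluripotency factors. Myelin genes had 35.9, and all marked coding genes 44.0. The random lists were not matched on signal, so narrow width was not told apart from weak signal. Among peaks above the median signal none of these 5 lists had the 5 marked genes the test needs. The call for myelin genes was lost in the pooled list (permutation adjusted p = 0.15), and that for pluripotency factors was lost without replicate 2 (0.16). The other 8 lists did not pass. Their medians ran from 1.62 kb for choroid plexus and ependyma and 1.67 kb for midbrain, hindbrain and spinal factors to 3.10 kb for oligodendrocyte precursors. Against CpG-matched lists oligodendrocyte precursors and GABA-A receptors (2.51 kb) passed as wider (permutation adjusted p = 0.047 each), and midbrain, hindbrain and spinal factors as narrower (0.04). Without merging the latter passed as narrower against random lists not matched on CpG class (1.29 kb, permutation adjusted p = 0.0023).

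**Figure D4:**
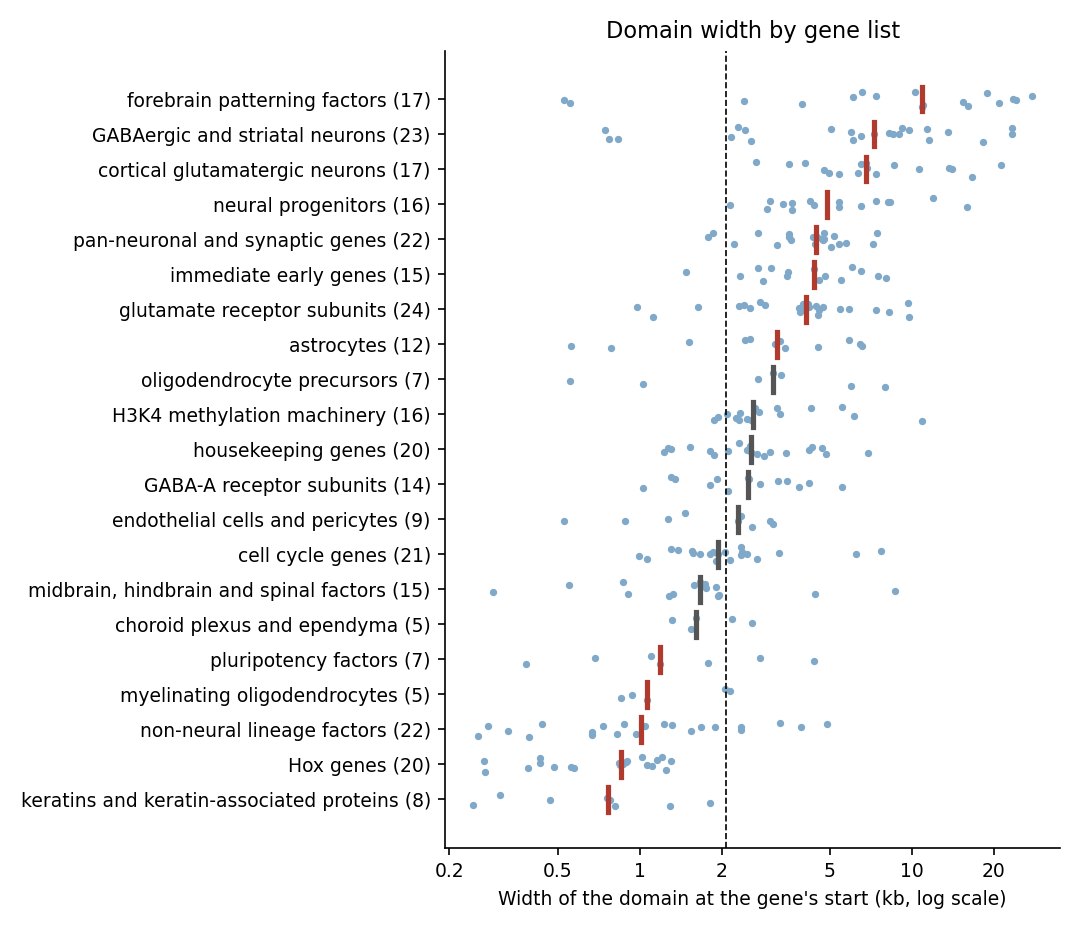
Width of the domain at each marked gene (points, kb, log axis) by list, with the number of marked genes in brackets and the list median as a vertical bar, red where the permutation adjusted p is under 0.05. The dashed line is the median of all marked coding genes, 2.08 kb, and the forebrain patterning factors have the widest median, 10.9 kb.

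Receptor and transporter genes of neurons showed a range of widths. Grin2b and Grin2a, NMDA receptor subunits, had domains of 9.55 kb ± 0.119 and 4.19 kb ± 0.119. Gabra2 had 5.10 kb ± 1.10 and Gabra1 3.58 kb ± 0.0283. The chloride transporter genes Slc12a2 and Slc12a5 had 4.52 kb ± 1.12 and 4.26 kb ± 0.27 (all SD, n = 2). Tubb3 and Neurod2 had 6.83 kb ± 0.799 and 6.03 kb ± 0.829. Narrow domains were found at Sst (0.987 kb ± 0.404) and Pvalb (0.721 kb ± 0.0502), markers of interneurons.

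Broad domains, from 4.75 kb upwards, numbered 706 and covered 767 coding genes. They held 14 of 17 marked cortical glutamatergic genes and 16 of 23 GABAergic and striatal genes (adjusted p = 1.2e-14 each, Fisher's exact test). They also held 13 of 17 forebrain patterning factors (4.9e-13), 8 of 16 progenitor genes (4.0e-06), 8 of 22 pan-neuronal genes (6.0e-05), 6 of 15 immediate early genes (0.00036) and 6 of 24 glutamate receptor genes (0.0054), in the same exact test. Of 28 lists, 7 were higher and none lower. No list could have passed as lower, since none had more than 24 marked members and broad domains are rare. Hox genes, with 0 of 20 against 5.36% of other marked genes, had an unadjusted p of 0.62 in Fisher's exact test. The call for glutamate receptors was lost without shared starts (adjusted p = 0.27, Fisher's exact test), and that for pan-neuronal genes at the widest 2% (0.23). Astrocyte genes, with 3 of 12 in broad domains (adjusted p = 0.082, exact), passed without replicate 1 (0.01), and the H3K4 methylation machinery, with 3 of 16 (0.14), passed without merging (0.037).

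Distal domains were short. Of all domains 3723 (18.4%) lay over 5 kb from any start, against 73.5% for random placement, with a median width of 0.65 kb and a signal of 6.01, against 1.92 kb and 40.2 for domains at starts. In the replicates the share was 20.95% ± 1.13 (SD, n = 2). The widest spanned 14.5 kb on chromosome 15 (85669013 to 85683487), inside Lncppara. Others lay on chromosome 13 near Trim27 (21166691 to 21173769), on chromosome 12 inside Bcl11b (107974549 to 107981488), on chromosome 3 near Gm22614 (96496762 to 96503576) and on chromosome 11 near Cbx8 (119052901 to 119058980). The domains near Trim27, inside Bcl11b and near Gm22614 had a RefSeq start within 1 kb. The domain inside Bcl11b measured 6.90 kb in replicate 1 and 2.75 kb in replicate 2, and that near Gm22614 measured 4.03 and 6.73 kb. Above the median signal 1.93% of domains were distal.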

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

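The tests of a lost peak, of missing starts and of the calling threshold were chosen only after their results were seen. So was the limit used to weigh CpG islands.

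Signal was present outside the peaks of the main comparisons, which used the replicated list on the chromosomes. The pooled list served only as an alternative. The replicated list held 18 peaks on 7 sequences outside the chromosomes, with a median signal of 5.79. The pooled list held 6062 peaks that are not in the replicated list, with a median width of 232 bp, a median signal of 2.90 and 24.6% within 1 kb of a start.

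Among 6698 CpG-rich coding genes, 34 had no replicated peak. Sequence shared with other copies, which leaves reads without a place, may account for many: a median of 21.04% of the 32-base words around their starts occurred once on the chromosomes, against 98.3% for marked CpG-rich genes, and 20 of the 34, such as Hist1h2ao and Entpd4, lay below the 5th percentile of marked genes. The other 14 lay at or above that percentile: 7 Hox genes and Ddx4, with a median of 99.25%, and Fkbp6, Hsf5, Meioc, Papolb, Slc25a31 and Zfp541, with 93.0 to 99.7%. Of these, 12 lay at or above the 25th percentile of marked genes (95.82%) and argue against shared sequence for their part. Fkbp6 (93.0%) and Hoxb7 (95.75%) lay below it, and shared sequence stays open for them. Of the 34, 20.6% had a peak in the pooled list or a replicate list that the replicated list does not hold. They include Hoxb5, Hoxb9, Hoxc11, Meioc and Zfp541 of the 14. For these genes a peak was left out in forming the replicated list. The others had no peak in any list to lose, so this step does not account for most of the 34. No biological explanation was tested.

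The 23 marked GABAergic and striatal genes, whose domains were wide as a list, had a low signal, a median of 22.9 against 45.7 in lists of equal width. This median lay at percentile 0 of 10000 random lists matched on width and at percentile 0 of those matched on CpG class. That argues against a general relation of enrichment to domain width and against promoter CpG class. The list was flagged for its low signal, the lowest median of the 8 wide lists, so both percentiles partly restate that choice. Low signal for the width was common to most of the 8 wide lists, the exceptions being pan-neuronal genes (percentile 31.88) and astrocytes (5.38). Progenitors lay at percentile 0, glutamate receptors at 0.46, cortical glutamatergic genes at 0.9, immediate early genes at 1.085 and forebrain patterning factors at 1.68. Against lists matched on CpG class these lay at 0.02, 33.8, 12.97, 2.935 and 0.71. CpG class therefore stays open for glutamate receptors, cortical glutamatergic genes and immediate early genes. CpG differences within a class were not tested. No biological explanation was tested.

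Distal domains made up 18.4% of the list. Starts that RefSeq holds and GENCODE lacks do not account for most, since 11.7% had a RefSeq start within 1 kb, against 1.97% at random. Starts absent from both annotations were not tested. Peaks near the calling threshold stay open: 96.8% held a peak with −log10 q of 3 or more, but so did 98.9% of all domains, the threshold is not known, and above the median signal the distal share was 1.93%. CpG islands away from starts may account for some of them: 4.73% held a 1 kb window meeting the CpG-rich limits (exact interval 4.07 to 5.46), against at most 0.142% in random placements. Distal domains had a median width of 0.65 kb. Shorter or less CpG-rich islands were not counted, so this share is no upper bound. The bound first written for this test, no more than random, was too strict to weigh islands as the main source. No biological explanation was tested.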

How the results depend on the processing

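The alternatives that left out genes with shared starts in the width, broad-domain and coding-share results, and that took 1 gene per domain, were chosen after seeing the data. The difference in marking between CpG-rich and CpG-poor promoters kept its direction and its call in all 8 alternatives (odds ratio 267.7 to 1168). Over 830 pairs of a list and an alternative, 789 stayed on their side of the threshold, and 30 of these changed direction with neither value past it. Another 22 lost their call and 16 gained one in the same direction, and 3 changed direction with 1 of the values past the threshold. No call turned into a call in the other direction. Of 18 lists called for marking, 7 kept their call against CpG-matched lists. Among those that lost it, the lists marked in full and the liver list, with none marked, held the most extreme share possible. The test could not have kept their call, so these losses by themselves decide nothing. The shares expected from CpG class were still close to those observed in the lists marked in full. They were 91.9 to 98.9%, against 65.2% of other coding genes. For the liver list 15.3% was expected, against 65.3% of other coding genes. Most of the difference of these lists from other genes thus went with CpG class. The cause of the changes below was not tested unless stated. Read depth is unknown, so what it limits cannot be given.

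Peaks above the median signal, a list with fewer peaks by construction, gave 96.9% of domains at starts, 52.8% of coding genes marked and 1.93% distal. They gave 4 lists higher and 15 lower in marking and 0 narrower in width, where none of the 5 narrower lists kept enough marked genes to be tested. Under them GABAergic and striatal genes (33.3%) lost their higher call and did not pass as lower. Oligodendrocyte precursors (12.5%) and midbrain, hindbrain and spinal factors (10.5%), not called in the replicated list, were called lower. CpG-matched lists gave 4 lists higher in marking.

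The share of domains at starts was 69.6 to 71.9% without 1 replicate, 68.4% in the pooled list, 76.5% with a 2 kb window, 65.7% with 1 start per gene, 70.8% without merging and 76.3% with a 3 kb gap. The share of coding genes was 65.4 to 65.5% without 1 replicate, 65.1% at −log10 q of 3, 66.1% pooled, 64.8% at 500 bp, 66.0% at 2 kb, 61.7% with 1 start and 56.7% without shared starts. The distal share was 20.2 to 21.8% without 1 replicate, 23.2% pooled and 13.5% beyond 10 kb.

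Overlap of replicate 1 and replicate 2 was 69.2 and 76.8% at 50% of both peaks, 78.5 and 81.1% at 50% of the peak counted, 91.4 and 90.8% at −log10 q of 3, and 89.0 and 92.35% for domains. Unshared peaks were 1999 and 2079 at −log10 q of 3, and 5000 in replicate 2 at 50% of the peak counted. The width correlation was 0.976 without merging and 0.948 with a 3 kb gap.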

Other observations

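These values were computed after the main results were seen, and no difference among them was tested. Marked genes of the X chromosome had a lower median signal than autosomal genes over all promoters, but not at CpG-poor ones. Leaving out olfactory, vomeronasal and keratin genes, the median signal of marked genes was 27.6 on the X chromosome and 44.7 on the autosomes. At CpG-rich promoters it was 31.0 for 116 genes against 51.2 for 6547, while the median widths were 2.47 and 2.41 kb. At intermediate promoters it was 28.2 against 39.7, and at CpG-poor promoters 19.2 for 99 genes against 16.5 for 1207. All 116 CpG-rich X-linked genes were marked. Both sexes were pooled. On the Y chromosome 4 coding genes were marked, Kdm5d, Eif2s3y, Uty and Ddx3y. Xist, the noncoding RNA of X inactivation, had a domain of 3.85 kb in replicate 1 and 3.31 kb in replicate 2.

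Most noncoding genes away from coding starts were unmarked, and processed transcripts were marked most often among the types counted. Over 5 kb from any coding start, 437 of 5134 long intergenic noncoding genes (8.51%), 92 of 1336 antisense genes (6.89%) and 100 of 358 processed transcripts (27.9%) were marked. Among processed pseudogenes it was 100 of 8908 (1.12%). Domains reached further into the gene than upstream of it. A median of 80.5% of a broad domain lay downstream of the gene's 5′ end for 373 genes with a start of their own, and 70.3% of other domains for 7389 genes. Separate domains at 2 or more starts were found for 1213 marked genes (8.47%), and Abr and Pde4d had 6 each.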
